A study of Mus musculus with 16 samples.

How the data were processed

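RNA from FACS-sorted GFP+ and GFP- cells of the olfactory mucosa of S100a5-tauGFP mice was measured on Clariom S arrays, 1 array per fraction of each pool of 3 mice, with 50 to 100 ng of total RNA made into biotinylated cRNA. Per the labels, 24 mice of both sexes aged 7 to 12 weeks were held singly for 40 h in chambers with clean air flowing at 3.1 L/min, and from 26 h on were given octanol or filtered air (vehicle) for 10 s every 20 min. The 4 groups (octanol GFP+, octanol GFP-, vehicle GFP+ and vehicle GFP-) hold 4 arrays each. The deposited values are log2 signals that the authors computed with Affymetrix Expression Console, and its version and settings are not given in the sources used here. They run from 2.22 to 18.70 log2 with array medians of 7.42 to 7.70, and were used as deposited.

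Of 28846 probe sets, 6577 are controls and 19572 of the rest carry exactly 1 gene symbol. Where several name 1 gene the probe set with the highest mean over 16 arrays was taken, which left out 67, so 19505 genes were tested, each matched by Entrez number to the RefSeq gene table of mouse assembly GRCm38.p6. That table was used for names and gene order only. The 2764 probe sets that are not controls and were not used gave 0 calls in limma for the octanol effect (smallest adjusted p = 0.490). Odorant receptors are genes with Olfr symbols (1091). Class I and class II were to be told by the current family symbols, but the tables carry the older ones, so class was taken from the MOR number among the synonyms: 1 to 42 class I (121), higher class II (950), none unclassified (20). The background level is the 95th percentile of the means of 321 vomeronasal receptor genes, whose cells lie outside this tissue for most receptors, and equals 6.32 log2. Above it lay 65.3 ± 1.17% of genes in octanol GFP+ arrays, 66.9 ± 0.343% in octanol GFP-, 64.5 ± 0.597% in vehicle GFP+ and 66.6 ± 0.285% in vehicle GFP- (SD, n = 4), and 993 receptors had a mean above it. A fold against a group with arrays under background is given as a bound, with values under background raised to it.

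The 24 mice make 8 pools of 3, so the GFP+ and GFP- arrays of 1 exposure and replicate number were taken to be the same mice. This is inferred from the number of mice, as the labels do not give it for each array. Residuals from group means were checked: the fractions of 1 pool correlated at 0.0779 to 0.222, 6 of 8 above 0.1, against a mean of -0.0532 for other pairs. Arrays of different mice that share a replicate number correlate about as much, so this check does not establish the pairing. Correlation of whole arrays was 0.981 to 0.987 within a group and 0.946 to 0.965 between the fractions of an exposure.

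The 5 comparisons were fitted with limma 3.58.1 (lmFit and eBayes, moderated t, 2-sided) in R 4.3.3. A fit of 16 arrays with the pool as a fixed block (6 residual degrees of freedom) gave the GFP+ against GFP- difference after vehicle, the same after octanol, and the octanol effect on the GFP+ to GFP- ratio, which is the difference between them. Octanol against vehicle within GFP+ cells and within GFP- cells was fitted on 8 arrays each. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and for the ratio also over receptors alone, with a threshold of 0.05. SE is the moderated standard error, and a p in the text is from limma unless another test is named. For octanol against vehicle, a gene whose values do not overlap between groups of 4 is counted, and chance gives 2.86%. For the fractions, a gene whose difference has the same sign in all 4 pools is counted, and chance gives 12.5%.

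Gene lists for 29 cell types and responses were written from background knowledge, of which 25 with at least 3 measured genes were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The lists are class I, class II, vomeronasal and trace amine receptors, genes raised or lowered by activity, immediate early genes, mature and immature neurons, odor signal termination, progenitors and cell cycle, horizontal basal, sustentacular, Bowman gland, microvillar and tuft, ciliated, glial, endothelial, fibroblast, myeloid, lymphoid, neutrophil and necklace cells, the stress response, and X and Y genes. Of the X and Y genes only 3 were measured, all Y-linked. Erythroid, dorsal zone and ventral zone markers and receptors with known ligands are described without a test. Camera tests a list against the other genes, while fry tests it against no difference, so the tests answer different questions. Fry values are given for part of the lists. Counts adjusted over a list alone are given where they differ from those over all genes.

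Genes are named by a rule: the 12 largest rises and falls past the threshold that go the same way in all 4 pools (fractions) or do not overlap (exposures), receptors past the threshold over receptors alone, up to 4 members of largest difference per list, S100a5 and Omp, and, where fewer than 5 genes pass, the 10 of smallest p as not past the threshold. The comparisons, lists, naming rule and all alternatives except 1 were chosen before the data were examined. Centring arrays on their receptors was added afterwards. The alternatives were quantile normalization, centring on the array median, a filter for genes above background in at least 4 arrays (13658 genes), every probe set, an intensity trend with robust variances, array weights, no block, the pool as a random block, the replicate number as a block, an adjusted p under 0.10, a 1.5-fold minimum, and leaving out each of 8 pools.

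The pipeline was tested on simulated data with 100 genes of each true fold among 19505. It recovered 46% of 2-fold and 91% of 4-fold effects on the ratio, 71% and 94% in GFP+ cells, 76% and 98% in GFP- cells, 66% and 100% between fractions after vehicle and 72% and 93% after octanol, with 0 of the wrong sign and 7 to 11 false calls per comparison. All changed genes of a comparison were planted together, which loosens the adjusted threshold relative to data with few changes. They were drawn at random over all genes, while receptors vary more (median SE of the ratio 0.33, against 0.198 for all genes). Structure by replicate number was not simulated. Recovery of a few responding receptors was therefore not measured and may be lower. A simulated 2-fold shift of the immature neuron list, with independent noise for each gene, was called by camera and 0 of the other 24 lists were. Correlation between the genes of a list was not simulated, so this does not measure false list calls in the data. Splits of 8 samples into 4 and 4 (35, each counted once with its mirror) were refitted to see what other groupings give. Single values were compared with exact permutation tests. Figures were drawn with matplotlib 3.10.9.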

Results

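GFP+ and GFP- cells were sorted from the olfactory mucosa of S100a5-tauGFP mice, whose reporter follows S100a5, a calcium-binding protein gene that rises with activity in olfactory sensory neurons. Each of 4 pools of 3 mice per exposure gave 1 GFP+ and 1 GFP- array, so 16 arrays measure 19505 genes, among them 1091 odorant receptor genes. Olfr95, an odorant receptor gene, was the 1 receptor whose GFP+ to GFP- ratio rose after octanol when p-values were adjusted over receptors alone. Adjusted over all genes it did not pass, and neither did any other gene. The sorted fractions themselves differed in many genes, 2871 higher and 2631 lower in GFP+ cells after vehicle, with receptors divided between them by gene identity. S100a5 was higher in GFP+ cells, by 0.82 log2 after vehicle and 0.86 after octanol, as the sort requires.

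After vehicle, the odorant receptor Olfr536 was 20.3-fold higher in GFP+ than in GFP- cells and the receptor Olfr1507 was 86.9-fold lower. Genes of neutrophils, monocytes and other blood cells were lowest of all in GFP+ cells: S100a8, a calcium-binding protein gene of neutrophils, was 311-fold lower. Fos and Egr1, immediate early transcription factors, and Gng8, a G protein subunit of immature sensory neurons, were also lower there. Omp, which marks mature sensory neurons, was measured near 18.1 log2 in both fractions.

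Among receptors higher in GFP+ cells after vehicle, Olfr613, a class I receptor, had the largest fitted difference, 4.62 log2 (SE 0.17, adjusted p = 7.87e-08, limma). Its GFP- mean of 6.19 ± 0.41 log2 (SD, n = 4) lay under the background of 6.32, with 1 of 4 arrays above it, so the receptor was at least 20.9-fold higher. Olfr536 reached 14.93 ± 0.33 log2 in GFP+ cells against 10.59 ± 1.00 in GFP- cells, a difference of 4.34 (SE 0.30). Olfr481 differed by 4.34 (SE 0.25), Olfr110 by 4.19, Olfr323 by 4.10, Olfr309 by 4.09, Olfr372 by 3.97 and Olfr101 by 3.92. Olfr424, Olfr494 and Olfr1093 followed at 3.88, 3.82 and 3.81, with Olfr494 above background in 2 and Olfr481, Olfr372 and Olfr1093 in 3 of 4 GFP- arrays, and Olfr520, with no GFP- array above background, at 3.75. All of these except Olfr613 are class II receptors, the group that most receptors of land vertebrates belong to. Olfr160, also known as M72, a receptor for acetophenone, was 8.94-fold higher in GFP+ cells, with 11.78 ± 0.33 log2 there and 8.62 ± 0.54 in GFP- cells.

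Other receptors were nearly confined to the GFP- fraction after vehicle. Olfr1384 (-6.69 log2, SE 0.27) averaged 6.72 ± 0.89 log2 in GFP+ cells, with 3 of 4 arrays above background, and 13.41 ± 0.12 in GFP- cells. Olfr390 differed by -6.69 (SE 0.30), Olfr1507 by -6.44 (SE 0.15) and Olfr1297 by -6.17 (SE 0.16). The class I receptors Olfr677 and Olfr69 differed by -4.96 (SE 0.37) and -4.02, and Olfr1440, or MOR215-1, a receptor for musk odorants, by -3.04.

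Over all genes, 2871 were higher and 2631 lower in GFP+ cells after vehicle, of 19505 tested. For 9303 genes (47.7%) the GFP+ minus GFP- difference had the same sign in all 4 pools, where chance gives 12.5%. Of the 1091 receptors, 470 were higher and 254 lower (502 and 281 when adjusted over receptors alone), with a median difference of 0.41 log2. Class I receptors gave 53 higher and 11 lower of 121, and class II receptors 413 higher and 236 lower of 950 (58 and 12, and 439 and 262, adjusted over each list alone). The class I list was shifted upwards as a whole (median 0.65 log2, camera adjusted p = 2.54e-05), but not with an estimated correlation (adjusted p = 0.526) or with arrays centred on their own median (adjusted p = 0.177). The class II list, at a median of 0.40, did not pass in camera (adjusted p = 0.102). In fry the adjusted p was 0.013 for class I and 0.00664 for class II. How the arrays are scaled sets the balance: the higher genes made up 52.2% of genes called as deposited, 65.0% after quantile normalization, 86.5% with each array centred on its median and 12.6% with each array centred on its receptors. For receptors the same shares were 64.9%, 67.1%, 73.0% and 55.4%. The median of all genes moved with it, from 0.13 as deposited to 0.46 with arrays centred on their median and -0.17 with arrays centred on receptors.

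**Figure D1:**
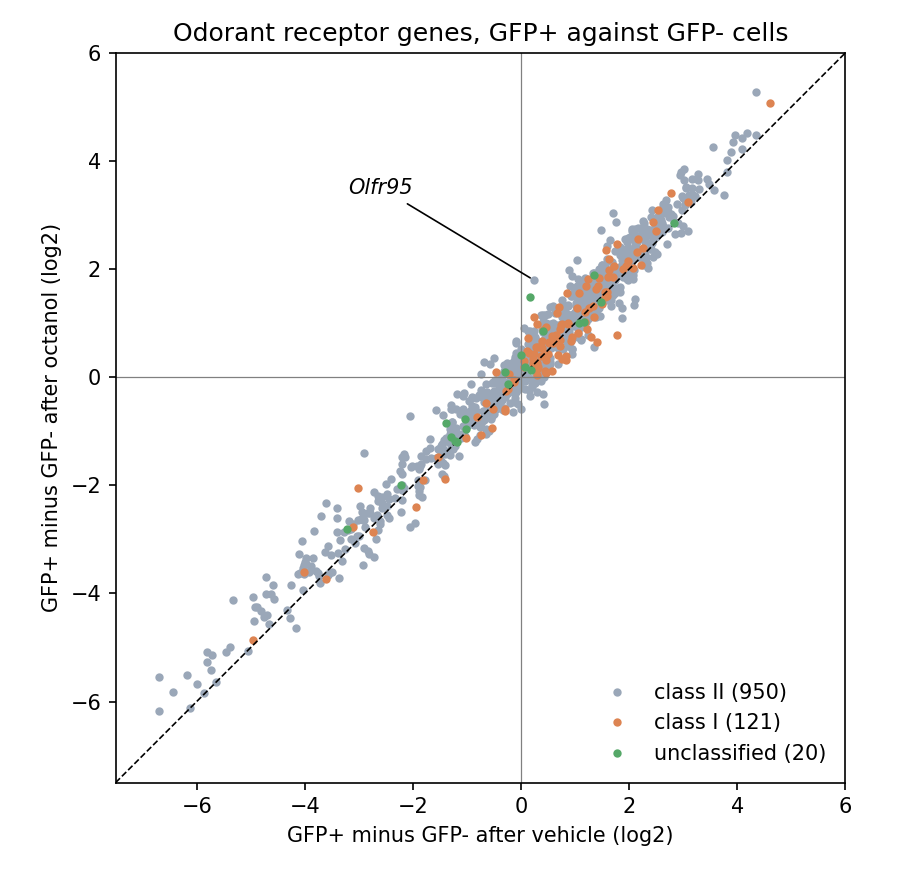
GFP+ minus GFP- difference (log2, mean of 4 pools) of each of 1091 odorant receptor genes after vehicle (horizontal) and after octanol (vertical), by receptor class, with the line of equality dashed. Receptors lie along the line in both directions, and Olfr95 lies above it.

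Genes that activity raises in olfactory sensory neurons were higher in GFP+ cells after vehicle, 6 of 9 past the threshold and 0 lower (median 0.74, camera adjusted p = 5.0e-04; 0.0688 with an estimated correlation, where the list call is lost). The list includes S100a5, which the sort selects, and also Pcdh10, a cell adhesion protocadherin (1.80 log2, 3.49-fold), Lrrc3b, a leucine-rich repeat gene (1.37), and Pcp4l1 (1.27). The genes lowered by activity showed 0 calls in 4 genes in limma, with a median of 0.08 (adjusted p = 0.904). Immediate early genes ran the other way, 11 of 17 lower and 0 higher (0 and 13 lower adjusted over the list alone; median -1.57, adjusted p = 2.22e-08, but 0.0977 with an estimated correlation): Fos by -5.05 log2, Btg2, an antiproliferative gene, by -4.14, Egr1 by -3.68 and Junb, a partner of Fos, by -3.37. Mature neuron markers were slightly higher (median 0.23, 5 of 14 higher, adjusted p = 0.0212, but 0.511 with an estimated correlation), led by Ano2, the chloride channel of olfactory cilia (0.50), and the receptor transporter Rtp2 and the mucosal gene Umodl1 (both 0.40), but their median turned to -0.07 with arrays centred on receptors. Genes that end the odor response were 4 higher and 1 lower of 6 (median 0.58, camera adjusted p = 0.241, fry adjusted p = 0.00225). The calcium exchangers Slc8a1 (1.05) and Slc24a4 (0.67) and the phosphodiesterase Pde1c (0.67) were higher. The kinase gene Grk3 had a fitted fall of -1.32. With 0 of 4 GFP+ and 3 of 4 GFP- arrays above background, it was at least 1.14-fold lower.

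Immature neurons, progenitors and other epithelial cells marked the GFP- fraction after vehicle. Of 12 immature neuron markers 9 were lower in GFP+ cells (median -1.58, adjusted p = 8.41e-09), with Gng8 at -5.03 log2, the actin regulator gene Ablim1 at -4.14 (under background in GFP+ cells), the axon growth gene Dpysl3 at -3.78 and Gap43, a growth cone protein, at -2.83. All 6 progenitor and cell cycle markers were lower (median -2.41, adjusted p = 5.81e-07, but 0.0570 with an estimated correlation), among them the proliferation marker Mki67 (-5.58, above background in 2 of 4 GFP+ arrays), Kit, a receptor of globose basal cells (-3.60, above background in 1 of 4), and the topoisomerase gene Top2a (-2.12, above background in 3). All 6 microvillar and tuft cell markers were lower as well (median -2.80, adjusted p = 1.87e-08): Trpm5, a taste-type cation channel, by -3.79, Foxi1, an ionocyte transcription factor, by -3.38 and the chloride channel Cftr by -2.84. Bowman gland markers were 4 of 5 lower (median -0.97, adjusted p = 0.001, but 0.0570 with an estimated correlation), led by the transcription factor Sox9 (-3.82), the water channel Aqp5 (-0.97) and the glutathione peroxidase Gpx6 (-0.86). Sustentacular markers were 3 of 6 lower (4 adjusted over the list alone; median -0.84, adjusted p = 0.0107, but 0.511 with an estimated correlation), all of them P450 genes: Cyp1a2 at -1.46, Cyp2a5 at -1.21 and Cyp2g1 at -0.98. Horizontal basal cell markers did not shift as a list (median -0.01, adjusted p = 0.612), and only Icam1, at or under background, was lower (-0.67).

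Blood cell genes had the largest falls after vehicle. Ly6c2, a monocyte surface gene, was at least 396-fold lower in GFP+ cells (-8.68 log2, SE 0.35), with 6.50 ± 0.30 log2 there and 15.18 ± 0.38 in GFP- cells. The neutrophil genes Retnlg (-8.35), S100a8 (-8.28, SE 0.52), Mmp8, a collagenase (-8.19, SE 0.41), Ngp (-8.19, SE 0.51), S100a9 (-7.91), Lcn2, an iron-scavenging lipocalin (-7.90), and Mmp9, a gelatinase (-7.33, under background in GFP+ cells), were lower too. So were Ly6c1 (-8.15), Fn1, a matrix gene of monocytes (-7.92, under background in GFP+ cells), the chitinase-like gene Chil3 (-7.60) and haptoglobin, Hp (-7.51), with Ly6c1 above background in 1 of 4 GFP+ arrays and Mmp8 and Hp in 2. All 7 myeloid markers (median -4.82, adjusted p = 4.72e-08), all 5 lymphoid markers (median -2.44, adjusted p = 2.85e-05) and all 4 neutrophil markers (median -8.05, adjusted p = 3.18e-07) were lower. As lists these 3 calls are lost in camera with an estimated correlation (adjusted p = 0.107, 0.0688 and 0.0688). In fry they passed (adjusted p = 6.49e-05, 9.04e-05 and 1.43e-05). Lyz2, a lysozyme of myeloid cells (-6.15), Fcer1g, an Fc receptor chain (-5.87), the leukocyte phosphatase Ptprc (-5.54) and the B cell gene Cd79a (-4.66) led them.

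**Figure D2:**
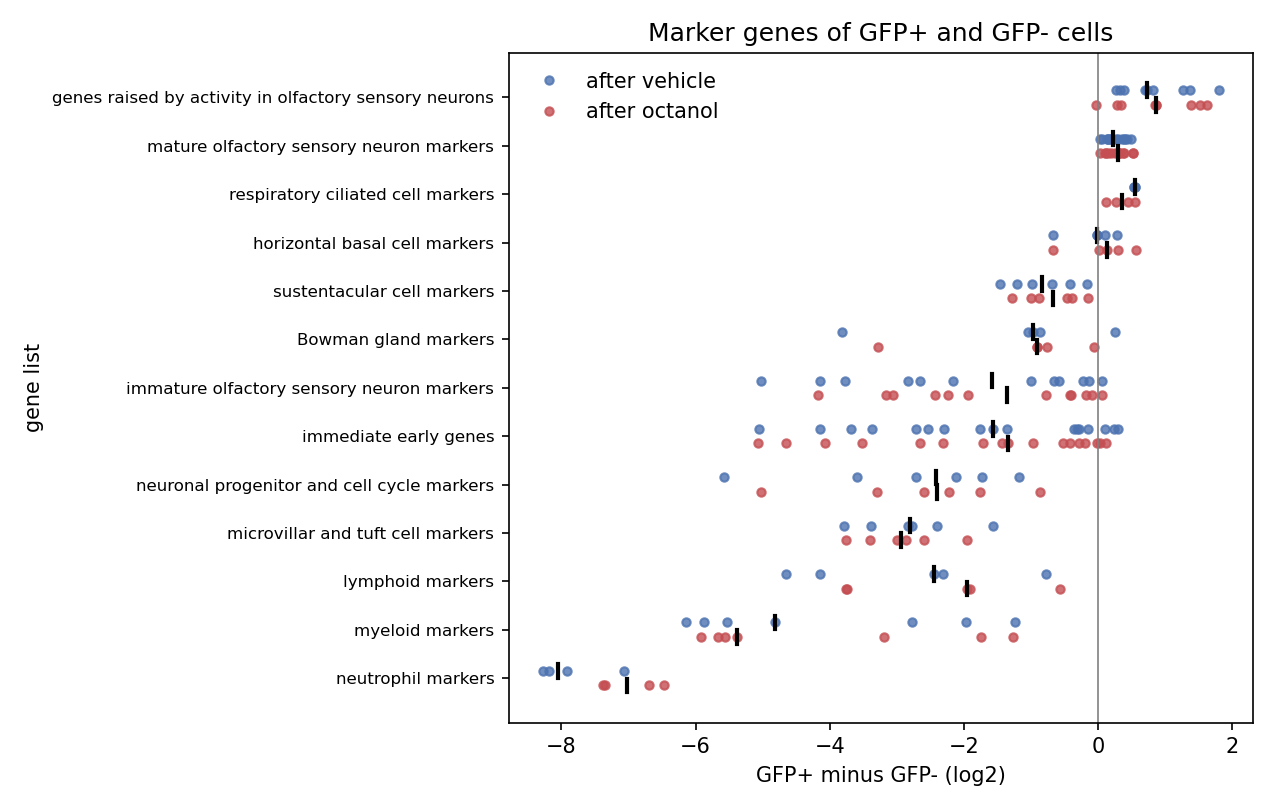
GFP+ minus GFP- difference (log2) of marker genes of 13 lists after vehicle and after octanol, with each dot a gene (mean of 4 pools) and each bar the list median. Blood cell, microvillar, progenitor and immature neuron markers are lower in GFP+ cells after both exposures. Mature neuron markers lie close to 0, but most of them are above 16 log2, near the top of the scale, where differences may be understated.

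After octanol the fractions differed in largely the same genes. Olfr481, a class II odorant receptor, and Olfr613, of class I, had the largest fitted rises in GFP+ cells, 5.27 and 5.07 log2, in an order that is not settled because both lie near background in GFP- cells. Ly6c2, a monocyte surface gene, was lower by -7.49, and its relative Ly6c1, with 2 of 4 GFP+ arrays above background, at least 165-fold lower. Immature neuron genes, cell cycle genes and Trpm5 of microvillar cells were lower in GFP+ cells here as after vehicle. Pcp4l1, raised by neuronal activity, was 3.10-fold higher.

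Olfr481 averaged 11.39 ± 0.46 log2 in GFP+ cells after octanol and 6.12 ± 0.56 in GFP- cells (SE of the difference 0.25), where 1 of 4 arrays lay above background, so it was at least 31.9-fold higher. Olfr613 (5.07, SE 0.17) was at least 26.1-fold higher, with 0 of 4 GFP- arrays above background. Olfr110 differed by 4.52, Olfr536 by 4.49, Olfr372 by 4.48, Olfr309 by 4.42 and Olfr101 by 4.35. Olfr1132 (4.26), Olfr323 (4.23), Olfr424 (4.17), Olfr494 (4.01) and Olfr490 (3.85) completed the 12 largest rises, all but Olfr613 in class II. Of these, Olfr490 was above background in 1, Olfr372 and Olfr494 in 2 and Olfr1132 in 3 of 4 GFP- arrays, so their fitted differences rest in part on values under background. Olfr160 was 12.8-fold higher. On the GFP- side, the receptors Olfr390 (-6.18, above background in 3 of 4 GFP+ arrays), Olfr1213 (-6.11), Olfr99 (-5.83) and Olfr1507 (-5.82, 56.4-fold) differed most, with Olfr677 (-4.87), Olfr629 (-3.73, above background in 1 of 4 GFP+ arrays) and Olfr69 (-3.61) the largest fitted differences of class I. Olfr629 was at least 8.96-fold lower, so its order against Olfr69 is not settled.

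In all, 3257 genes were higher and 2569 lower in GFP+ cells after octanol. For 9217 genes (47.25%) the difference had the same sign in all 4 pools, where chance gives 12.5%. Receptors gave 514 higher and 236 lower (549 and 265 adjusted over receptors alone), with a median of 0.58 log2. Class I gave 53 higher and 13 lower (62 and 13 adjusted over the list alone; median 0.70, adjusted p = 2.52e-05), a shift that was lost with an estimated correlation (adjusted p = 0.559) and with arrays centred on their own median (adjusted p = 0.0678). Class II gave 455 higher and 217 lower (480 and 245; median 0.56, adjusted p = 0.0135, but 0.530 with an estimated correlation), and the direction of its test against other genes turned with arrays centred on their own median, where its median was 0.83. Higher genes were 55.9% of those called, 63.4% after quantile normalization, 84.9% with arrays centred on their median and 5.78% with arrays centred on receptors, and for receptors 68.5%, 69.1%, 74.2% and 51.8%. The all-gene median was 0.14 as deposited, 0.41 centred on the array median and -0.36 centred on receptors. Between the exposures, 1775 genes were higher in GFP+ cells after both (479 by chance), 2299 lower after both (347 by chance) and 2 called in opposite directions. Among receptors 452 were higher after both, 224 lower after both and 0 opposite in limma.

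Of genes raised by activity, 6 of 9 were higher after octanol (median 0.86, adjusted p = 0.0012, but 0.0757 with an estimated correlation): Pcp4l1 by 1.63 log2, Pcdh10 by 1.52, Lrrc3b by 1.39, and both S100a5 and the adhesion gene Kirrel2 by 0.86. The 4 genes lowered by activity had a median of 0.12 (adjusted p = 0.955). Immediate early genes were 12 of 17 lower (median -1.34, adjusted p = 4.53e-09, but 0.0757 with an estimated correlation), with Fos at -5.07, Btg2 at -4.65, Egr1 at -4.06 and Junb at -3.51. Mature neuron markers were 7 of 14 higher (median 0.30, adjusted p = 0.0135, but 0.512 with an estimated correlation; -0.20 with arrays centred on receptors), with Ano2 and the vesicular glutamate transporter Slc17a6 both at 0.52, Rtp2 at 0.39 and Umodl1 at 0.38. Genes that end the response did not pass in camera (4 higher and 1 lower of 6, 4 and 2 adjusted over the list alone; median 0.65, adjusted p = 0.266), while the fry adjusted p was 0.0011. Slc8a1 was at 1.03, Pde1c at 0.73 and Slc24a4 at 0.72. Grk3 was at -1.05 in the fit. With 0 of 4 GFP+ and 2 of 4 GFP- arrays above background, it was at least 1.14-fold lower.

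Immature neuron markers were 9 of 12 lower after octanol (median -1.36, adjusted p = 3.08e-08), with Gng8 at -4.18, Dpysl3 at -3.16 and the transcription factor Sox11 at -2.43, and Ablim1, with 0 of 4 GFP+ arrays above background, at least 3.11-fold lower. Progenitor markers (median -2.40, adjusted p = 8.88e-07; Mki67 -5.02, Kit -3.30, Top2a -2.22) and microvillar markers (median -2.93, adjusted p = 5.68e-09; Trpm5 -3.76, Foxi1 -3.40, Cftr -3.00) were lower, with Kit above background in 1, Top2a and Trpm5 in 2 and Cftr in 3 of 4 GFP+ arrays. Bowman gland markers (median -0.91, adjusted p = 5.75e-04; Sox9 -3.28, Gpx6 -0.91, Aqp5 -0.76) and sustentacular markers (median -0.67, adjusted p = 0.0172, but 0.530 with an estimated correlation; Cyp1a2 -1.28, Cyp2a5 -0.99, Cyp2g1 -0.88) were also lower. Horizontal basal cell markers had a median of 0.13 while their test ran downwards (adjusted p = 0.955), and Icam1, under background in GFP+ cells, was again lower (-0.67), while Trp63, under background in every array, was higher (0.57). Myeloid (median -5.39, adjusted p = 3.08e-08; Fcer1g -5.92, Lyz2 -5.66, Ptprc -5.39), lymphoid (median -1.96, adjusted p = 1.11e-04; 4 of 5 lower, 5 adjusted over the list alone; Cd79a -3.74) and neutrophil markers (median -7.03, adjusted p = 5.83e-07) were lower in GFP+ cells. These 3 list calls are lost in camera with an estimated correlation (adjusted p = 0.0973, 0.0757 and 0.0757). In fry they passed (adjusted p = 6.05e-05, 2.57e-04 and 2.11e-05). Among the 12 largest fitted falls were Ly6c1 (-7.57), Mmp9 (-7.56), Ly6c2 (-7.49), Hp (-7.40), S100a8 (-7.38), the antimicrobial peptide gene Camp (-7.36), Mmp8 (-7.35) and Fn1 (-7.31), with Mmp9 and Fn1 above background in 1 of 4 GFP+ arrays, Ly6c1, Hp and Camp in 2 and Mmp8 in 3, so that their order is not settled. The B cell gene Cd37 (-6.93, above background in 1 of 4 GFP+ arrays), Ifitm6, a membrane gene of myeloid cells (-6.83), Retnlg (-6.80) and Chil3 (-6.79) followed. With an estimated correlation between genes, the camera calls that hold after octanol are immature neurons (adjusted p = 0.0457 with an estimated correlation), progenitors (0.0457), Bowman glands (0.0457), microvillar cells (0.0173) and vomeronasal receptors (0.0457). After vehicle, immature neurons (adjusted p = 0.0462 with an estimated correlation) and microvillar cells (0.0203) hold.

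Olfr95 was the 1 odorant receptor whose GFP+ to GFP- ratio passed for octanol, adjusted over receptors alone. This class II receptor was about equal in both fractions after vehicle and 1.80 log2 higher in GFP+ cells after octanol. Olfr715b, an unclassified receptor, and the class II receptors Olfr738 and Olfr1151 had the next smallest p among receptors and did not pass the threshold. For S100a5 and Omp the effect was 0.04 and 0.05 log2, neither past the threshold, and the sign for S100a5 turned to -0.16 with arrays centred on receptors.

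Olfr95 differed between GFP+ and GFP- cells by 1.80 ± 0.39 log2 in octanol pools (2.14, 2.13, 1.49 and 1.44) and by 0.24 ± 0.29 in vehicle pools (0.39, 0.33, -0.20 and 0.43; SD, n = 4 pools). The octanol effect was 1.56 log2 (SE 0.22, 95% interval 1.06 to 2.06, 2.95-fold), with an adjusted p of 0.0483 over 1091 receptors and 0.863 over all genes. Most of it came from GFP- cells, where the mean was 10.32 log2 after octanol and 11.54 after vehicle, against 12.12 and 11.77 in GFP+ cells. With each array centred on its receptors the effect was 1.36 log2 and the adjusted p 0.0986, and over the alternatives other than left-out pools the adjusted p ranged from 0.002 to 0.647. The call rests on the fixed pool block: in limma the adjusted p over receptors was 0.647 without it and 0.299 with the pool as a random block.

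**Figure D3:**
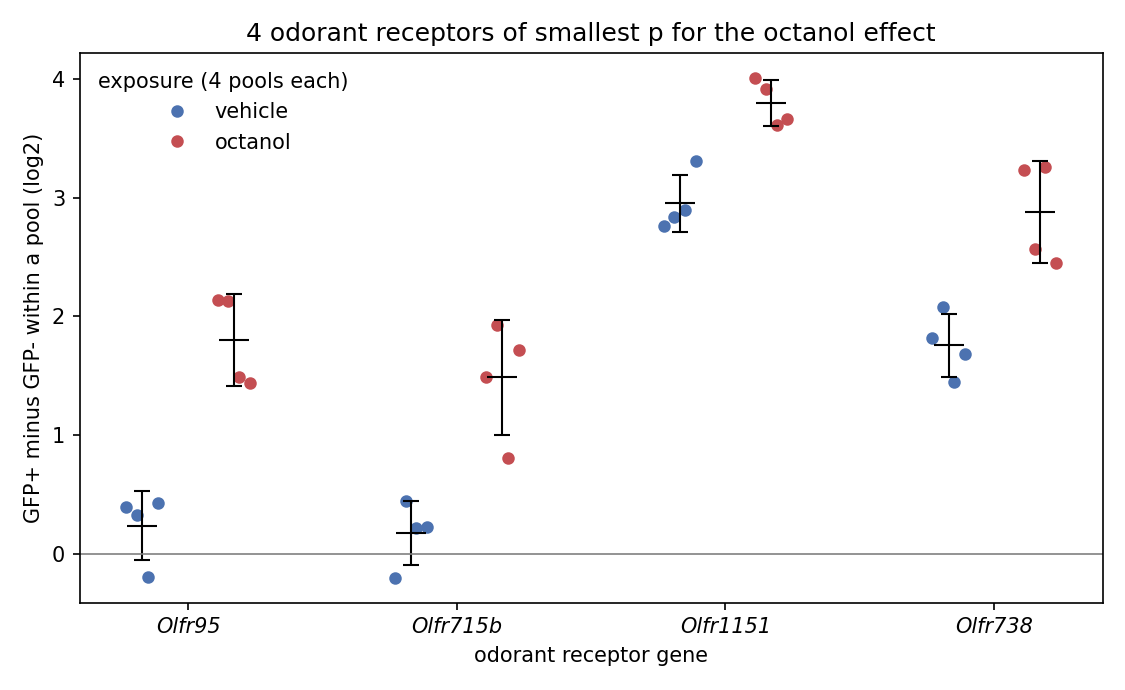
GFP+ minus GFP- difference within each pool (log2) of the 4 odorant receptor genes of smallest p for the octanol effect, after vehicle and after octanol (dots, 4 pools each; bars, mean and SD). Pools of the exposures do not overlap for the genes shown, but only Olfr95 passed, and over receptors alone.

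No gene passed over all 19505 genes in limma (smallest adjusted p = 0.863), while 886 had an unadjusted p under 0.05, 505 with a higher and 381 with a lower ratio after octanol. Pools of the exposures did not overlap for 504 genes, or 2.58%, where chance gives 2.86%. Among receptors 65 had a higher and 9 a lower ratio at an unadjusted p under 0.05, and the median of all receptors was 0.17 log2, with 72.4% above 0, and 0.0926 without pool octanol 1. Olfr715b (1.31, SE 0.25, adjusted p = 0.192 over receptors), whose paralog Olfr715 was not told apart from it here, had pool differences of 1.49 ± 0.49 after octanol and 0.17 ± 0.27 after vehicle. Olfr738 (1.12, SE 0.23) had 2.88 ± 0.43 and 1.76 ± 0.27, and Olfr1151 (0.85, SE 0.17) had 3.80 ± 0.19 and 2.95 ± 0.24. Olfr1115 (0.79) and Olfr769 (-0.71) followed without passing, as did Olfr1128, with 0 of 8 GFP- and 1 of 4 octanol GFP+ arrays above background. Larger but more variable estimates, also not past it, were those of Olfr292 (1.502), Olfr1153 (1.32) and, in class I, Olfr610 (-0.99), Olfr611 (0.96) and Olfr620 (0.88), and of these only Olfr611 was above background in every array. The other genes of smallest p, Gm11110 (1.07), Krt39 (-0.83), Prl7a2 (-1.03) and Havcr1 (0.93), lay under background, 4930412O13Rik (0.86) lay close to it, and the tetraspan gene Tm4sf19 (-0.75) was above it in 1 of 4 vehicle GFP- arrays.

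Class II receptors shifted upwards as a list (median 0.18, mean 0.19, 699 of 950 above 0, camera adjusted p = 6.56e-04), as did immature neuron markers (median 0.23, 11 of 12 above 0, adjusted p = 0.00153). Neither held with an estimated correlation (adjusted p = 0.887 and 0.766 with an estimated correlation) or in the rotation test fry (0.848 and 0.346). Centring arrays on receptors, 950 of 1091 of them class II, removes such a shift by construction and cannot test it (median -0.02). Among immature markers Gng8 (0.85), Dpysl3 (0.62) and Gap43 (0.59) did not pass alone, nor did Ablim1, which was under background in every GFP+ array. Class I receptors did not pass as a list (median 0.10, camera adjusted p = 0.646). Genes raised by activity (median 0.02, adjusted p = 0.929) and immediate early genes (median -0.11, adjusted p = 0.594) did not either, with Pcp4l1 at 0.36, Pcdh10 at -0.28, Nr4a1, an activity-dependent nuclear receptor, at 0.42 and Btg2 at -0.51.

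Within GFP+ cells, octanol left no gene past the threshold against vehicle. The odorant receptor Olfr769 had the smallest p and was lower after octanol by -0.997 log2, short of the threshold. S100a5, the gene the reporter follows, differed by -0.10 and the mature neuron gene Omp by 0.04. Neutrophil genes, S100a8 and S100a9 among them, were higher as a list, a camera call that is lost with an estimated correlation (adjusted p = 0.656).

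In GFP+ cells limma called 0 of 19505 genes (smallest adjusted p = 1.00), with 727 at an unadjusted p under 0.05, 440 higher and 287 lower after octanol. The values of the exposures did not overlap for 431 genes (2.21%, where chance gives 2.86%). Receptors gave 26 higher and 16 lower at that unadjusted level and 0 adjusted over receptors alone in limma, with a median of 0.01. Olfr769 (SE 0.15) reached an adjusted p of 0.0827 over receptors, and Olfr725 (0.65, SE 0.13) was also above background in GFP+ cells. Kcnt1, a sodium-activated potassium channel gene also not past the threshold, was above background in 4 of 4 vehicle and 0 of 4 octanol GFP+ arrays. These counts give no size for the difference. After vehicle, with 1 of 4 GFP- arrays above background, it was at least 1.19-fold higher in GFP+ than in GFP- cells. The others of smallest p, Cd96 (-0.73), Gm5065 (0.62), Klrb1c (0.86), Cxcl2 (0.60), Olfr108 (-0.86), Ccr2 (1.04) and Mypn (0.51), had means under background there.

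Neutrophil markers rose as a list in GFP+ cells (median 1.54, 4 of 4 above 0, camera adjusted p = 0.00681): Ngp by 1.89 log2, S100a9 by 1.69, S100a8 by 1.38 and Camp, near background, by 0.11, with 1 gene past the threshold over the list alone. Bowman gland markers (median 0.50, adjusted p = 0.0218; 2 of 5 past the threshold over the list alone; Gpx6 0.57, Sox9 0.53, Aqp5 0.50, and Sox10 -0.26 under background) and horizontal basal cell markers (median 0.24, adjusted p = 0.0352; the keratin genes Krt14 0.32 and Krt5 0.24 and the transcription factor Trp63 0.29, all with means under background) were higher too. Each of these 3 lists had an adjusted p of 0.656 with an estimated correlation. Egr1 was the 1 immediate early gene to pass over its list alone, at -0.50 log2 (SE 0.11). Class I receptors (median -0.05), class II receptors (0.02) and genes raised by activity (0.05) did not pass as lists. Sustentacular markers (median 0.32, 6 of 6 above 0, camera adjusted p = 0.0996) did not pass either.

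Within GFP- cells, octanol likewise left no gene past the threshold. Nhlh1, a transcription factor of immature olfactory neurons, and the odorant receptors Olfr715b and Olfr95 were among the genes of smallest p, all lower after octanol. Receptors as a family lay lower as deposited (centring arrays on receptors removes this by construction), and so did immature neuron markers such as Gng8 and Gap43. These list calls are lost with an estimated correlation (adjusted p = 0.540 for each). S100a5 differed by -0.15 log2 and Omp by -0.01.

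In GFP- cells limma called 0 genes (smallest adjusted p = 0.982), with 894 at an unadjusted p under 0.05, 394 higher and 500 lower after octanol. The values of the exposures did not overlap for 501 genes (2.57%, where chance gives 2.86%). Receptors gave 9 higher and 110 lower at that level and 0 adjusted over receptors alone in limma. Nhlh1 differed by -0.82 log2 (SE 0.15), Olfr715b by -0.97 (SE 0.18) and Olfr95 by -1.22 (SE 0.26, adjusted p = 0.360 over receptors). Polrmt, the mitochondrial RNA polymerase, differed by -0.77, the phosphatase gene Ppm1l by -0.65, the inflammasome adaptor gene Pycard by 0.57 and the transcription factor gene Lmx1a by 0.57. Cacng2 (0.56), Eng (-0.86) and Cyp3a11 (-0.73) lay under background.

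Class II receptors were lower as a list in GFP- cells (median -0.16, 219 of 950 above 0, camera adjusted p = 8.41e-09). Class I receptors were lower by a median of -0.13 (adjusted p = 0.0153). With arrays centred on receptors the medians are -0.01 and 0.02, which that centring fixes near 0 by construction. Immature neuron markers were lower in all 12 genes (median -0.27, adjusted p = 1.6e-05), with Ablim1 at -0.78, Gng8 at -0.52, Gap43 at -0.42 and Dpysl3 at -0.41. Ensheathing glia markers (median 0.37, adjusted p = 0.0180; the brain lipid-binding gene Fabp7 0.41 and the Wnt antagonist Frzb 0.44, the latter under background) and neutrophil markers (median 0.44, adjusted p = 0.0153; S100a8 and S100a9 both 0.48) were higher. None of these 5 lists held with an estimated correlation (adjusted p = 0.540 with an estimated correlation for each), and no single receptor or marker passed. Whether receptors fell in GFP- cells differently from GFP+ cells is what the ratio above tests, at 0.17 log2 in the median.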

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

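The tests of Olfr95 with a pool left out and of its neighbours, of the receptor shift with a pool left out and of mature markers, and of the neutrophil share and neutrophil shift with a pool left out were chosen after the result was seen.

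Olfr95 had a higher GFP+ to GFP- ratio after octanol (1.56 log2), in a set where 1 of 1091 receptors passed over receptors alone. No single pool sets the size of the estimate, since the lowest with a pool left out was 1.42 log2 (without vehicle 3, lower 95% bound 0.92). The call itself was lost without any pool other than octanol 3, with limma adjusted p over receptors up to 0.214. The tables argue against a shift shared by all receptors, since centring arrays on receptors left 1.36 (bound 0.87). They also argue against signal shared with neighbouring receptor genes, whose median effect was 0.0841 over 10 genes, with Olfr91 highest at 0.54. Chance cannot be excluded: 9 of the 35 splits of the 8 pools gave as many receptors, the real one giving 1 and the highest of the others 47. Sequence shared with receptors elsewhere was not tested, and the call ends in several alternatives, with the estimate at 1.36 to 1.56 log2 outside left-out pools. An octanol response of cells that carry Olfr95 may be proposed as a hypothesis only.

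The split with 47 receptors sets pools 1 and 2 against pools 3 and 4, and gave 9 genes for the ratio, 14 within GFP+ cells and 0 within GFP- cells in limma, which points to a structure of the samples that follows the replicate numbers. Neither the splits nor the exact permutation tests here take that structure into account. With the replicate number as a block across exposures, 2 receptors passed for the ratio and the adjusted p of Olfr95 was 0.0467 (range over alternatives other than left-out pools 0.002 to 0.647).

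Receptors were lower in GFP- cells after octanol (median -0.16 log2), which with immature neuron markers also makes the class II and immature shifts of the ratio. The receptor median per GFP- array was 9.43 ± 0.12 log2 after octanol and 9.58 ± 0.15 after vehicle (exact permutation p = 0.171), and the median over receptors of the GFP+ minus GFP- difference of each gene was 0.57 ± 0.14 and 0.43 ± 0.05 per pool (exact permutation p = 0.0286, the smallest possible), while the differences between array medians overlap. Mature markers under 16 log2 had a median of 0.0137 in GFP- cells (4 markers, SD 0.059), and all 14, most of them above 16 log2, had -0.0152 with 3 above 0. Neither value is a fall as large as the -0.16 of receptors. The SD is between genes and not between pools, so a small fall in the share of all sensory neurons is not excluded. A lower share of immature neurons in the GFP- fraction may be involved and cannot be told apart from other causes: receptors higher in GFP- cells differed by -0.0364 from those higher in GFP+ cells, a value that neither requires nor forbids it. Whether pool octanol 1 decides the shift stays open as well, since without it the median was -0.11, where the SE of the array medians is 0.0845.

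Neutrophil markers were higher in GFP+ cells after octanol (median 1.54 log2, 4 of 4 genes). A larger share of GFP- cells in that fraction may be involved, although the sort on GFP should remove them. The other 147 genes at least 16-fold higher in GFP- cells, receptors left out, rose by a median of 0.30 log2 (quartiles 0.10 to 0.47). An added share of 0.517%, itself estimated from the neutrophil genes, predicts 0.28 (Spearman over genes 0.656). The 82 of them above background in vehicle GFP+ cells rose by 0.31 where 0.26 is predicted (Spearman 0.740). The vehicle GFP+ mean of a gene enters both its prediction and its measured rise, so part of both correlations is built in. The 147 genes include other neutrophil and monocyte genes, such as Retnlg, Mmp8 and Ly6c2. A rise of those cells alone could give such values, so they cannot tell it from a larger share of all GFP- cells. The most abundant of the marker genes, S100a9 and S100a8, averaged 16.63 and 16.44 log2 in octanol GFP- cells and 9.93 and 9.06 in octanol GFP+ cells. Without octanol 4 the marker median was 1.00 (SE of the array means without that pool 0.55), so whether that pool decides the rise stays open. The array means were 9.10 ± 1.10 log2 after octanol and 7.83 ± 0.67 after vehicle (exact permutation p = 0.171), and more neutrophils after octanol were not tested apart from the sort.

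Where octanol called 0 genes in limma, the splits decide nothing, since all 35 of 35 give at least 0 whatever the data: the highest other was 9 for the ratio (886 genes at an unadjusted p under 0.05), 14 for GFP+ cells (727) and 1 for GFP- cells (894). For the fractions no other split came near the real one. In fits of the 8 arrays of each exposure without a block, 4566 genes were called after vehicle and the highest other split gave 2. After octanol 4562 were called, with 0 as the highest other, and 1 of the 35 splits in each was as large. Among the 8 splits that part all 4 pools, the highest other was 0 for both exposures. With only 8 such splits, the real one included, the splits alone cannot exclude chance, and the calls rest on limma.

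In 9 of 174 groups of 4 values 1 lay apart by Dixon's test, and about 5% of groups do so by chance. Camp differed between the fractions of octanol 1 by -8.00 log2, the other octanol pools by -7.19 to -7.08. Olfr95 differed by -0.20 in vehicle 3, the other vehicle pools by 0.33 to 0.43. Krt39, under background, differed by 0.56 in vehicle 3 (others 0.83 to 0.88). The gene 4930412O13Rik differed by 0.33 in octanol 3, the octanol pool where it was above background in both fractions (others 0.74 to 0.80). The class II receptor mean was 9.66 in vehicle GFP+ 3 (others 9.79 to 9.82). Immature neuron markers averaged 10.67 in octanol GFP+ 1 (others 10.76 to 10.77). Sustentacular markers averaged 12.07 in octanol GFP- 4 (others 12.83 to 12.95). Stress response genes averaged 12.89 in octanol GFP+ 4 (others 12.74 to 12.76). The median over receptors of the difference was 0.79 in octanol 1 (others 0.485 to 0.509). Between exposures, the effects on the ratio that stood apart were Olfr95 (1.56), class II receptors (0.18) and immature neurons (0.23).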

How the results depend on the processing

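The alternative with arrays centred on their receptors and the tests made with it were chosen after the result was seen.

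The single receptor call for the ratio is fragile. No receptor passed with arrays centred on their median, with arrays centred on receptors, with dim genes left out, with array weights, without a block or with the pool as a random block (0 each in limma), 2 passed with an intensity trend and robust variances and 2 with the replicate number as a block across exposures, and 1 passed in the other alternatives. Leaving out pools gave 0 to 2, with 2 without octanol 3 and 0 without any of the others. Over all genes 1 gene passed with the trend and robust variances. Olfr95 itself was 1.499 log2 (adjusted p over receptors 0.0766) centred on medians, 1.36 (0.0986) centred on receptors, 1.56 (0.0512) without dim genes, 1.48 (0.0652) with array weights, 1.56 (0.647) without a block and 1.56 (0.299) with a random block. Leaving out pools gave 1.42 to 1.68 log2 with adjusted p from 0.0407 (without octanol 3) to 0.214. The cause was not tested.

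The exposures are different mice and not every pair of 1 replicate number correlated above 0.1, so the number was not taken to pair them. The fractions of 1 pool, 6 of 8 above 0.1, would not meet that rule either, and were paired by the count of mice. The data point to something shared within a number, as the second principal component separates numbers 1 and 2 from 3 and 4. With the number as a block, limma called 0 genes within GFP+ cells and 0 within GFP- cells. Pools of 1 number correlated across exposures at 0.0582 to 0.230 in GFP+ cells (3 of 4 above 0.1) and 0.0719 to 0.332 in GFP- cells (3 of 4), and at 0.0236 to 0.250 in the pool differences (2 of 4). Arrays that correlated best with their own number were 4 of 8 in GFP+ cells and 7 of 8 in GFP- cells.

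Counts between the fractions follow the scaling. After vehicle the 2871 higher genes became 4561 with quantile normalization, 12759 centred on medians, 630 centred on receptors, 1201 with a 1.5-fold minimum and 1724 to 2882 with a pool left out (1724 without vehicle 4, 1836 without vehicle 1). The 2631 lower became 4387 centred on receptors, and 2275 to 2614 with a pool left out. After octanol the 3257 higher became 11401 centred on medians, 536 centred on receptors, 1306 with a 1.5-fold minimum and 1799 to 3115 with a pool left out (1799 without octanol 1, 1970 without octanol 4). The 2569 lower became 8740 centred on receptors, and 2170 to 2555 with a pool left out. The 236 lower receptors became 363 centred on receptors, and 199 to 251 with a pool left out. Without a block the counts were 2456 and 2535 after vehicle and 2806 and 2474 after octanol, and with a random block (correlation 0.18) 3280 and 2766, and 3688 and 2663.

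Of the named genes, 1826 of 1912 alternative values after vehicle and 1859 of 1931 after octanol kept their call, with 85 and 65 weaker. Reversed values all came after octanol with arrays centred on receptors: Rtp2 -0.11, Umodl1 -0.12, Tekt1 -0.0569, Dnajb9 -0.19, Atf5 -0.21 and Omp -0.38.

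Of lists, class II receptors after octanol turned in their test with arrays centred on medians, with a median of 0.83, and class I receptors within GFP+ cells turned to 0.28 without vehicle 2 and became a call at -0.17 without vehicle 3. For the ratio, without octanol 1 the class II shift was 0.11 (adjusted p = 0.104) and the immature shift 0.19 (0.0583). In GFP+ cells the neutrophil call was lost without octanol 4 (1.00, adjusted p = 0.0607), the Bowman gland call without octanol 2 (0.0522), octanol 3 (0.0605), vehicle 2 (0.0509) and vehicle 4 (0.120), and the horizontal basal call after quantile normalization (0.0643) and without octanol 2, 3 or 4 or vehicle 1, 2 or 4. In GFP- cells the class I call was lost without octanol 1 (-0.03), vehicle 2 or vehicle 4 and with array weights (0.182), the neutrophil call without octanol 1 (0.20, 0.227), octanol 4, vehicle 1 or vehicle 2 and centred on receptors (0.110), and the glia call after quantile normalization, without dim genes and without octanol 1, octanol 2 or vehicle 2. Mature markers lost their call between fractions with quantile normalization and centred on receptors, for both exposures, and without vehicle 4 (0.0528 after vehicle), vomeronasal receptors lost theirs with quantile normalization, and sustentacular markers without vehicle 2 (0.0568 after vehicle), octanol 1 (0.0843 after octanol) or octanol 2 and centred on receptors (0.0594 and 0.227).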

Other observations

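The tests of pool composition by Y-linked genes were chosen after the result was seen.

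Trace amine receptors, a family of amine detectors in olfactory neurons, were divided between the fractions as odorant receptors were. Taar4, a receptor for phenylethylamine, was higher in GFP+ cells by 2.90 log2 after vehicle and 3.28 after octanol, Taar9 by 2.01 and 2.41 and Taar7b by 1.68 and 1.71, while Taar2 was lower by -2.51 and -2.44. Of 14 genes 6 were higher and 3 lower after vehicle (7 and 4 adjusted over the list alone; median 0.77, adjusted p = 0.201) and 7 higher and 2 lower after octanol (8 and 3; median 1.22, adjusted p = 0.128). None passed the threshold for the octanol effect on the ratio, with Taar3 at 0.54, Taar9 at 0.40 and Taar4 at 0.38 the largest estimates (median 0.23, 12 of 14 above 0).

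Receptors with known ligands also differed between the fractions. Olfr73, or mOR-EG, a eugenol receptor, was lower in GFP+ cells by -1.07 log2 after vehicle and -0.91 after octanol. Olfr558 (0.75 after vehicle), a class I receptor, and Olfr2, or I7, a receptor for octanal (-0.45 after octanol), did not pass. The octanol effect on the ratio was 0.51 for Olfr160, -0.42 for Olfr558, 0.29 for Olfr690 and 0.16 for Olfr73, none past the threshold. Olfr78 was not measured among the genes tested here.

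Red cell genes were lower in GFP+ cells, Slc4a1, the anion exchanger of erythrocytes, by -3.33 log2 after vehicle and -3.22 after octanol and Alas2, of haem synthesis, by -2.24 and -2.08, while globin genes were not measured among the genes tested here. Zone markers did not pass: of the dorsal zone Nqo1 differed by 0.23 and 0.32 and Acsm4 by 0.24 and 0.33, and of the ventral zone Nrp2 by 0.28 and 0.36 and Ncam2 by 0.26 and 0.38. Necklace neuron markers, of cells that sense with guanylate cyclase D, had a median of -0.37 after vehicle (adjusted p = 0.119) and -0.45 after octanol (0.0193, but 0.0973 with an estimated correlation), with Pde2a, their phosphodiesterase, at -3.14 and -3.19 and the carbonic anhydrase gene Car2 at -0.75 and -0.71.

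Respiratory ciliated cell genes were slightly higher in GFP+ cells after vehicle, 3 of 4 past the threshold (median 0.55, adjusted p = 0.0782; Tekt4 0.56, Tekt1 0.55), and after octanol 2 of 4 were (median 0.36, adjusted p = 0.264; Tekt1 0.44, which turns to -0.0569 with arrays centred on receptors). Fabp7 was the 1 glial gene higher after vehicle (0.52; list median 0.43, adjusted p = 0.273), and after octanol the glial list had a median of 0.14 and a mean of -0.01 (adjusted p = 0.955). Endothelial markers had medians of -0.03 (adjusted p = 0.355) and -0.08 (0.165), with Pecam1, under background in GFP+ cells, at -0.93 and -0.67. Fibroblast markers had a median of 0.01 and a mean of -0.08 after vehicle (adjusted p = 0.612; the matrix gene Dcn -0.81 was lower, but not adjusted over the list alone) and a median of -0.39 after octanol (0.288).

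Stress response genes did not shift as a list: after vehicle 2 were higher and 1 lower of 12 (median 0.04 and mean 0.05, test downwards, adjusted p = 0.904), and after octanol 2 higher and 1 lower (1 and 1 adjusted over the list alone; median 0.05, mean -0.00, adjusted p = 0.699). Xbp1, a transcription factor of the unfolded protein response, was lower by -0.56 and -0.50, Trib3 higher by 0.54 after vehicle, Dnajb9, a chaperone gene, higher by 0.32 and 0.31 and Atf5, which the receptor choice feedback uses, higher by 0.28 after octanol. Dnajb9 and Atf5 turn to -0.19 and -0.21 after octanol with arrays centred on receptors.

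Vomeronasal receptors, which set the background here, were 36 higher and 2 lower of 321 after vehicle (5 and 0 adjusted over the list alone; median 0.26, adjusted p = 0.0107, but 0.0570 with an estimated correlation) and 45 higher and 0 lower after octanol (13 and 0; median 0.28, adjusted p = 0.00406, and 0.0457 with an estimated correlation). Their medians turn to -0.04 and -0.21 with arrays centred on receptors, so a direction at this level of signal rests on the scaling. Vmn1r222 (0.95) and Vmn1r212 (0.87) after vehicle and Vmn2r1 (0.95) and Vmn2r45 (0.93) after octanol had the largest fitted differences, and of these only Vmn2r45 was above background in all 4 arrays of a fraction.

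Lists not given above for the octanol effect on the ratio had these medians and no call: vomeronasal receptors 0.05, genes lowered by activity 0.01 (mean -0.01, test downwards), mature neurons 0.02, signal termination 0.06, progenitors 0.21, horizontal basal cells 0.03, sustentacular cells 0.14, Bowman glands 0.13, microvillar cells -0.13, ciliated cells -0.20, glia -0.38 (adjusted p = 0.111), endothelium -0.12, fibroblasts -0.28, myeloid cells -0.02, lymphoid cells 0.41, neutrophils 1.06 (adjusted p = 0.234), necklace cells -0.12, stress response -0.01 and Y-linked genes 0.05 (mean -0.02, test downwards). Lymphoid markers in GFP- cells had a median of -0.52 (adjusted p = 0.0871).

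The level of Y-linked genes followed the replicate number in part, but the fractions of pool 2 differ by nearly 1 log2 in both exposures, so the sex composition of the pools is not established. The mean of 3 Y-linked genes was 10.0, 9.61, 9.33 and 11.0 log2 in GFP+ arrays of octanol pools 1 to 4 and 10.3, 9.78, 9.08 and 11.1 in those of vehicle pools 1 to 4, and 10.4, 8.63, 8.97 and 10.9 and 10.3, 8.89, 9.22 and 10.7 in GFP- arrays. The first principal component (75.7% of variance) separates the fractions and the next (4.06%) separates every array of replicate numbers 1 and 2 from those of 3 and 4. The 3 Y-linked genes did not differ between the fractions as a list (median 0.38, camera adjusted p = 0.612 after vehicle, and 0.22, 0.699 after octanol).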
